A study of Mus musculus with 3 samples.

How the data were processed

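The samples were 3 libraries of ribosomal-RNA-depleted chromatin RNA from bone marrow-derived macrophages of C57BL/6J mice, stimulated for 15 min with 100 ng/ml of lipid A, per the labels. They form 1 group, with the replicate numbers given in the labels. The labels give a fragment size range of 250 to 400. No comparison between groups was possible, and no control library was used here.

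For each library 3 tables were used. The deposited gene table and a deposited transcript table give expected counts, which need not be whole, and TPM, per the file headers. The authors' transcript table also gives the percent of each gene's abundance that each isoform takes. A further deposited transcript table gives estimated counts and TPM of an independent quantification, called the second quantification. The assembly was mm10 and the annotation GENCODE M21, per the labels and the text deposited with the tables. The aligner, the counting programs and their versions are not given in the sources used here, and neither is the use of strand, so a gene and an antisense partner may share reads. TPM was set by the authors to a sum of 1000000 over all features of a table. The gene table holds 81881 features: 55536 annotated genes, all of which matched GENCODE M21, 26248 features with numeric IDs, 96 ERCC spike-ins, all at 0 counts, and 1 phiX genome. The annotated genes held 98.2%, 99.6% and 99.5% of the expected counts in replicates 1, 2 and 3. Of the transcripts, 141862 of the first table and 141767 of the second matched the annotation. The second quantification held 1.67 ± 0.0836 times as many counts as the gene table (SD, n = 3).

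Depth was 10974934 to 21376404 expected counts per library. The floor was set at 3 counts; floors and percents cover counting error only, since reads without molecular identifiers are not independent molecules. Where a list or gene value is given in TPM, the table's own TPM was used; list statistics used log2(TPM + 1), which understates differences of low genes.

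There were 24 gene lists, fixed with their members before the data were examined. They cover rapid early response, NF-kB feedback and subunits, early cytokines and chemokines, secondary response, interferon response, the TLR4 pathway, macrophage markers, 7 lists of other cell types, proliferation, chromatin and nuclear non-coding RNA, cytoplasmic non-coding RNA, mitochondrially encoded mRNA, ribosomal protein mRNA, housekeeping genes, replication-dependent histones, heat shock and stress, Y-linked genes, and RNA processing and transcription machinery. Ahsp, Morrbid, Rn7sl1 and Norad had no match by symbol and were not used. The level of a list is its median, set against 10000 random lists of as many protein-coding genes. It was called high in the top 2.5% of these lists, and low in the lowest 2.5%, only if the mean and each of the 3 libraries were on that side. Differences between lists were differences of medians per library, with the percentile among 10000 relabellings of the genes. The deviation of a list in a library is the median over its genes of log2(TPM + 1) minus the mean of the 3 libraries, given relative to the median of 10000 lists matched on mean expression in 20 bins. It used protein-coding genes with a mean TPM above 0, and lists with at least 5 of them, 21 lists in all; these limits were set after the data were seen. Percentiles describe these libraries and are not p-values over animals.

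Genes were named by a rule fixed before the data were examined. It takes the 4 highest members of each list, and the 2 lowest members of the rapid early, NF-kB, early cytokine, secondary response and interferon lists. It adds 20 fixed genes, the 10 highest protein-coding and 5 highest other genes, and the 10 protein-coding genes with the largest SD of log2(TPM + 1) among those with a mean TPM of at least 5 and at least 50 counts in a library. Outside this rule, Cx3cr1, Cd3e, Cd3g, mt-Rnr2, Neat1, Kcnq1ot1, Egr2, Egr3, Fosb, Cd3d, Thy1, S100a8, S100a9, Gm42418 and CT010467.1 were chosen after their values were seen. Some genes that the rule takes, mainly markers of other cell types near the floor, are not printed.

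Expected counts were rounded to whole numbers for edgeR 4.0.16, which gave TMM factors and the common dispersion without any group term, and for DESeq2 1.42.0, which gave size factors; both ran in R 4.3.3. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The steps were tested on simulated data. For the dispersion, a simulated coefficient of variation of 0.3 was recovered as 0.296. For list deviations, counts of 22028 protein-coding genes were drawn from the libraries' means and sizes, with a coefficient of variation of 0.25 and 200 genes in lists of 20 raised in replicate 1. Of these, 3 of 3 lists raised 1.25 times, 3 of 3 raised 1.5 times, 2 of 2 raised 2 times and 2 of 2 raised 4 times were called, and so were 12 of 200 lists of unchanged genes. Before being set relative to matched lists, the mean deviation was 0.17 for 0.21 simulated, 0.34 for 0.39, 0.58 for 0.67 and 1.28 for 1.33 (log2). It was -0.05 for lists of unchanged genes. The relative deviation, which is the one reported, was not compared with its simulated size. For levels, 20 of 20 lists drawn from the most expressed 25% of genes and 1 of 100 random lists were called. The simulated genes were independent of each other, unlike real ones. This test was written after the list statistics had first been computed, and it does not cover the matching on GC content, length or differences between replicates.

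The alternatives tried were a pseudocount of 0.1, other minimum levels, the second quantification, the posterior mean TPM the authors deposited, TMM-scaled counts per 1000000, DESeq2 size factors, and leaving out each replicate. After the data were seen, 3 more were added: TPM scaled to a sum of 1000000 over protein-coding genes, matching on GC content and length as well as expression, and leaving out each replicate from the deviations. The minimum mean TPM of 1 in the counts of members highest in a library and in the retained-intron medians, and the choice of the lists whose deviations are treated as main results, were also made after the data were seen.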

Results

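RNA bound to chromatin was measured in macrophages grown from the bone marrow of C57BL/6J mice, after 15 min with 100 ng/ml of lipid A. Lipid A is the part of bacterial lipopolysaccharide that the receptor TLR4 recognises. The chromatin fraction of a cell holds transcripts still being made or kept at the DNA, so its RNA reports mostly on recent transcription. Ribosomal RNA was depleted and the remaining total RNA was sequenced. The series holds 1 group of 3 biological replicates, and no unstimulated library was analysed here. The values therefore give the state of the chromatin RNA at this time, not a change from rest. The replicates carry the same donor label and separate sample labels, so their spread may hold less than the spread between animals. Starting RNA was 1 µg in replicate 1, 250 ng in replicate 2 and 500 ng in replicate 3. The gene tables held 10974934, 21376404 and 14376665 expected counts in replicates 1, 2 and 3. At 1 TPM (transcripts per 1000000) or more, 9345 protein-coding genes were detected in all 3 libraries and 10768 in at least 1, while 6645 had no count in any. For a gene with an effective length of 1 kb, 3 counts were worth 0.221 TPM in replicate 1, 0.0948 in replicate 2 and 0.191 in replicate 3, which is taken as the floor.

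Transcripts of the immediate early genes were abundant on chromatin. Of the 30 rapid early response genes, 29 had a TPM of at least 1 in all 3 libraries, and the median of the list was 45.2 ± 14.7 TPM (SD, n = 3). Fos, a subunit of the AP-1 transcription factor, stood at 287 ± 31.1 TPM (SD, n = 3), the highest of the list. It was followed by the phosphatase gene Dusp1 at 183 ± 69.2 TPM, the mRNA decay factor Zfp36 at 170 ± 81.6 TPM and the kinase gene Plk2 at 158 ± 48.3 TPM (SD, n = 3 each). Junb was at 118 ± 36.9 TPM, Egr1 at 59 ± 45.4 TPM and Ier2 at 56.9 ± 9.75 TPM (SD, n = 3 each). The lowest members were Arc, at 0.147 ± 0.1 TPM, and Plk3, at 1.36 ± 0.186 TPM (SD, n = 3 each). The list's median lay at percentile 100.0 among 10000 random lists of as many protein-coding genes, in the mean and in each library.

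All 22 genes of NF-kB feedback and NF-kB subunits were also detected in all 3 libraries, with a list median of 29.6 ± 14.1 TPM (SD, n = 3) at percentile 100.0. Tnfaip2 was highest at 569 ± 354 TPM. Nfkbia, which encodes the inhibitor IkBa, was at 147 ± 87 TPM, Sod2 at 135 ± 135 TPM and Pim1 at 124 ± 49.6 TPM (SD, n = 3 each). The mean of Sod2 rests mainly on replicate 1, with 288, 38.1 and 77 TPM in replicates 1, 2 and 3. Nfkbib, at 4.6 ± 2.54 TPM, and Traf1, at 5.59 ± 2.34 TPM, were the lowest members.

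Early cytokine and chemokine genes divided into a detected and an undetected part. Of the 19 genes, 13 had a mean TPM of at least 1. Il1b was highest at 102 ± 115 TPM, then Cxcl2 at 88.9 ± 69.5 TPM, Tnf at 75.8 ± 70.8 TPM and Ccl4 at 42.1 ± 19.6 TPM (SD, n = 3 each). Ptgs2, which encodes the inducible cyclooxygenase, was at 12.8 ± 11.7 TPM (SD, n = 3). Ccl20 had no count in any library and Csf2 was at 0.04 ± 0.0693 TPM (SD, n = 3). The SDs of Il1b and Tnf were close to their means, with the highest value in replicate 1. Il1b was at 234 TPM in replicate 1, 26.7 in replicate 2 and 43.7 in replicate 3, and Tnf at 156, 22.6 and 48.6 TPM. The list's median was 12.3 ± 11.8 TPM (SD, n = 3), at percentile 99.7 for the mean of the libraries. In replicate 2 alone its percentile was 93.58, outside the top 2.5% required in each library, so the list was not called high. Without replicate 2 it was called high, at percentile 99.98.

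Genes that lipopolysaccharide switches on late in macrophages included several cytokine genes near the floor. Of the 20 secondary response genes, 8 had a mean TPM of at least 1, and the list median was 0.652 ± 0.318 TPM (SD, n = 3), at percentile 51.07 among all protein-coding genes. With list and background limited to genes with a mean TPM of at least 0.1, which left 17 of 20 members, the percentile was 0.16, called low, so the rank of this list depends on the genes counted. Il6 had 16, 1 and 7 expected counts in replicates 1, 2 and 3, Il12b had 4, 6 and 13, and Nos2, the inducible nitric oxide synthase, had 11, 7 and 8. Il12a and Ccl22 had none. The members with the most RNA were Il15 at 19.6 ± 8.58 TPM, Il18 at 8.57 ± 2.39 TPM, Acod1 at 4.13 ± 2.7 TPM and Cd40 at 3.32 ± 1.58 TPM (SD, n = 3 each). In the second quantification 13 members had a mean TPM of at least 1, and Il15 was at 159 ± 82.8 TPM (SD, n = 3). The median of the rapid early genes exceeded that of the secondary response genes by 4.78 ± 0.26 on the log2(TPM + 1) scale (SD, n = 3). The difference was 5.07, 4.71 and 4.56 in replicates 1, 2 and 3, and the mean was at percentile 100.0 among 10000 relabellings of the genes. With 3 libraries the smallest exact two-sided sign-flip p is 0.25, so no p over libraries is given.

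Interferon-stimulated genes were present while the gene of interferon beta was not detected above the floor. Ifnb1 had 1, 0 and 1 expected counts in replicates 1, 2 and 3. Cxcl9 and Cxcl11 were each at 0.0167 ± 0.0289 TPM, against 0.652 ± 0.377 and 2.15 ± 0.617 TPM in the second quantification (SD, n = 3 each). Stat2, a transcription factor of the interferon pathway, was at 114 ± 23.5 TPM, Oasl2 at 107 ± 47 TPM and Oas2 at 90.2 ± 30.5 TPM (SD, n = 3 each). Of the 28 members annotated as protein-coding, 25 had a TPM of at least 1 in all libraries, and the list median of 15.2 ± 5.7 TPM (SD, n = 3) was called high. Early cytokines minus interferon response genes gave a difference of medians of -0.62 ± 0.92 (log2, SD, n = 3), at percentile 19.29. The sign differed between libraries, at 0.43 in replicate 1, -1.27 in replicate 2 and -1.04 in replicate 3, so the order of these lists was not resolved. On TMM-scaled counts per 1000000 the difference was -1.66, at percentile 1.14, which is called.

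**Figure D1:**
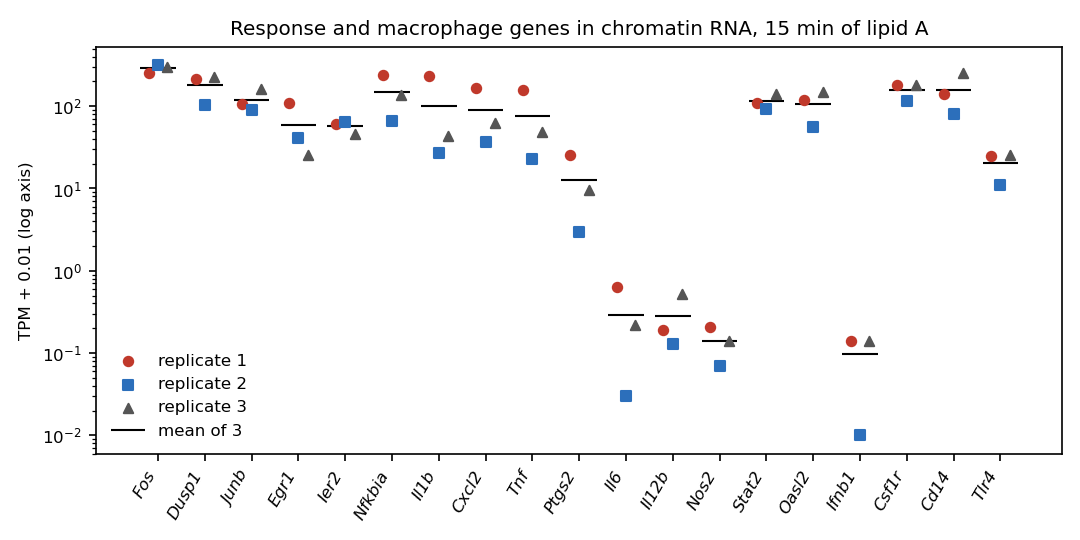
TPM of response and macrophage genes per library on a log axis, with 0.01 added so that values of 0 can be drawn; points are the 3 replicates and lines their means. Fos lies between 252 and 312 TPM, Il1b, Cxcl2, Tnf and Ptgs2 are highest in replicate 1, and Il6, Il12b, Nos2 and Ifnb1 stay below 1 TPM.

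The macrophage programme was strongly represented. Of 30 macrophage markers, 29 had a TPM of at least 1 in all libraries, and the list median was 40.9 ± 12.4 TPM (SD, n = 3), at percentile 100.0. The lysosomal protease genes Ctsb and Ctsd were at 508 ± 74.8 and 247 ± 27.2 TPM, the lysozyme gene Lyz2 at 189 ± 96.8 TPM and the galectin gene Lgals3 at 180 ± 41.2 TPM (SD, n = 3 each). Csf1r, the receptor for the growth factor that maintains macrophages, was at 159 ± 37.4 TPM (SD, n = 3). Cx3cr1 alone was near 0, at 0.0133 ± 0.0115 TPM (SD, n = 3). In the second quantification all 30 markers had a mean TPM of at least 1, and Lgals3 was at 1977 ± 618 TPM (SD, n = 3).

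Genes of the TLR4 pathway were also called high, with 31 of 33 at a TPM of at least 1 in all libraries and a list median of 17.2 ± 6.28 TPM (SD, n = 3). Ikbke was at 250 ± 32.5 TPM, the co-receptor gene Cd14 at 156 ± 86 TPM, Tbk1 at 94.7 ± 20.8 TPM, Map3k8 at 75.8 ± 42.4 TPM and Tlr4 itself at 20.5 ± 8.25 TPM (SD, n = 3 each). Among all protein-coding genes the highest means belonged to Gpnmb, Lilrb4a, Lilr4b, Hnrnpa2b1, Sat1, Ddx5, Zeb2, Fth1, Tcirg1 and Rsrp1. Gpnmb, a lysosomal glycoprotein gene, was at 1191, 712 and 1410 TPM in replicates 1, 2 and 3. Lilrb4a and Lilr4b are neighbouring, similar receptor genes on chromosome 10, so the division of reads between them is uncertain.

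Most markers of other cell types were low in the gene table, and more of them reached a mean TPM of 1 in the second quantification. In the gene table, none of the 16 neutrophil and granulocyte precursor markers and none of the 11 mast cell and basophil markers reached a mean TPM of 1. Ngp was the highest neutrophil marker at 0.497 ± 0.144 TPM, followed by Mmp8 at 0.467 ± 0.202 TPM, Prtn3 at 0.317 ± 0.355 TPM and Camp at 0.213 ± 0.162 TPM (SD, n = 3 each). Kit was the highest mast cell marker at 0.563 ± 0.307 TPM (SD, n = 3). Of 16 T and NK cell markers 3 reached a mean TPM of 1, led by Il7r at 39.5 ± 11.5 TPM and Cd4 at 5.75 ± 2.07 TPM (SD, n = 3 each), while Cd3e and Cd3g had no count. The B cell list had 2 such genes, led by Cr2 at 1.75 ± 1.06 TPM. The dendritic cell list had 2, led by Ccr9 at 1.62 ± 0.78 TPM. The erythroid and megakaryocyte list had 2, led by Alas2 at 7.74 ± 2.28 TPM, and the stromal and endothelial list had 1, Kdr at 2.91 ± 1.35 TPM (SD, n = 3 each). None of these lists was called low in level. Their percentiles were 15.85 for neutrophil, 3.58 for T and NK cell, 2.52 for B cell, 34.0 for dendritic cell, 14.9 for erythroid, 22.43 for stromal and 4.04 for mast cell markers. A low call could not be reached here, since many protein-coding genes had no count. In replicate 1, lists of 11 to 16 genes with a median of 0 TPM already stood at percentiles 4.22 to 8.92. The missing call therefore says nothing about these cell types. With lists and background limited to genes with a mean TPM of at least 0.1, the neutrophil list (7 of 16 members left) and the stromal list (10 of 16) were called low, and the B cell and mast cell lists had too few members left for a value. In the second quantification the members with a mean TPM of at least 1 were 3 neutrophil, 7 T and NK cell, 5 B cell, 5 dendritic cell, 4 erythroid, 6 stromal and 1 mast cell markers. There Cd3d was at 16.1 ± 4.35 TPM, Cr2 at 12.2 ± 4.88 TPM, Fcer2a at 10.9 ± 3.46 TPM, Thy1 at 10.2 ± 3.39 TPM and Alas2 at 19.5 ± 6.46 TPM (SD, n = 3 each), against 0.00667, 1.75, 0.573, 0.103 and 7.74 TPM in the gene table. The level of these genes therefore depends on the quantification. Of these lists, only that of B cell markers was called low in the second quantification. Cell cycle genes were at a list median of 2.35 ± 0.79 TPM and heat shock and stress genes at 3.98 ± 0.288 TPM (SD, n = 3 each), at percentiles 86.62 and 92.3, neither called. With lists and background limited to genes with a mean TPM of at least 0.1, which left 24 of 24 and 17 of 18 members, these percentiles were 3.59 and 49.03, neither called. Pcna, at 29.2 ± 5.36 TPM, led the first list and Hspa8, at 102 ± 50.2 TPM, the other (SD, n = 3 each). Xist, the RNA that coats the inactive X chromosome, was at 1057 ± 119 TPM (SD, n = 3). Ddx3y had 0, 1 and 0 expected counts in replicates 1, 2 and 3, and no Y-linked gene of the list of 6 reached a mean TPM of 1 in the gene table, against 3 in the second quantification.

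**Figure D2:**
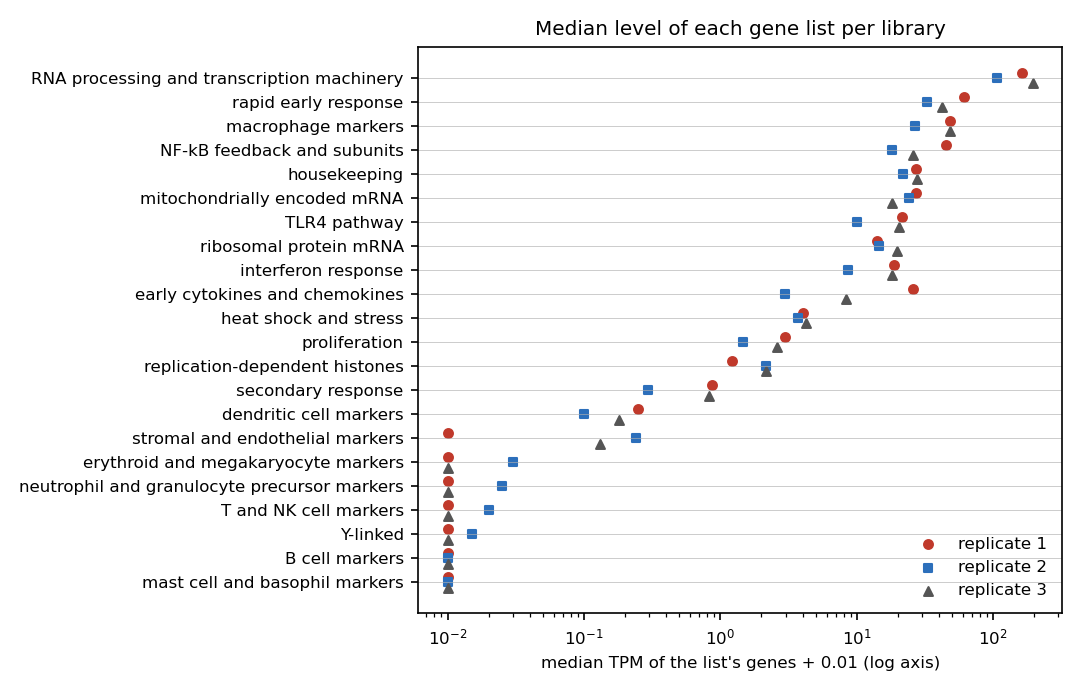
Median TPM of each list of protein-coding genes per library, on a log axis with 0.01 added; each point is 1 library. The RNA processing list is highest (105.6 to 194.6 TPM), the rapid early list stands at 32.5 to 61.3 TPM, and the secondary response list stays below 1 TPM.

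Of the lists of protein-coding genes, that of the splicing and transcription machinery had the highest median. All 35 genes had a TPM of at least 1 in all libraries, with a list median of 154 ± 45 TPM (SD, n = 3). Hnrnpa2b1 was at 787 ± 154 TPM, Ddx5 at 709 ± 212 TPM, Rbm39 at 635 ± 157 TPM and Srsf5 at 442 ± 92.4 TPM (SD, n = 3 each). The 31 ribosomal protein genes, whose mRNAs are stable and abundant in the cytoplasm, had a list median of only 16 ± 3.21 TPM (SD, n = 3). Rpl10 was at 125 ± 17.1 TPM, Rpl3 at 73.4 ± 16 TPM, Rpl5 at 38.6 ± 11.9 TPM and Rpl7a at 33.5 ± 1.29 TPM (SD, n = 3 each). Ribosomal protein minus RNA processing genes gave a difference of medians of -3.16 ± 0.33 (log2, SD, n = 3), at percentile 0.0, with -3.44, -2.79 and -3.24 in replicates 1, 2 and 3. Both lists lay at percentile 100.0 against random protein-coding genes.

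Housekeeping genes were at a median of 25.6 ± 3.23 TPM (SD, n = 3), led by Eef1a1 at 255 ± 71.3 TPM, Actb at 246 ± 126 TPM and Actg1 at 171 ± 63.1 TPM (SD, n = 3 each). Mitochondrially encoded mRNAs were at a median of 23 ± 4.63 TPM (SD, n = 3), with mt-Co1 at 183 ± 74.7 TPM and mt-Atp8 at 146 ± 96.6 TPM (SD, n = 3 each). Replication-dependent histone genes were at 1.84 ± 0.541 TPM (SD, n = 3), led by Hist2h2ac at 15.4 ± 4.72 TPM and Hist1h1c at 8.03 ± 4.08 TPM; copies of these genes are similar, so single values are uncertain. The housekeeping and mitochondrial lists were called high, the latter not on TMM-scaled counts per 1000000, where it stood at percentile 95.52.

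Genes annotated as non-coding took a large part of the reads. Protein-coding genes held 66.3 ± 5.36% of the expected counts of annotated genes and long intergenic non-coding RNA genes 26.8 ± 5.59% (SD, n = 3 each). Malat1, a long RNA retained in nuclear speckles on chromosome 19 from 5795690 to 5802672, took 9.73 ± 2.05% of counts (SD, n = 3). Neat1, the scaffold of paraspeckles, took 2.58 ± 0.94% and Xist 1.62 ± 0.228% (SD, n = 3 each). Gm26917, annotated as a long intergenic RNA on chromosome 17 from 39843013 to 39846341, took 10.8 ± 7.43%, and its neighbour Gm42418 took 1.24 ± 0.805% (SD, n = 3 each). These genes lie beside or opposite an annotated ribosomal RNA gene, and whether their reads come from ribosomal RNA was not resolved, so the part of the long intergenic share that is nuclear non-coding RNA is uncertain. In TPM, Malat1 was at 22300 ± 9167, Rn7sk at 7268 ± 3530 and Neat1 at 2206 ± 370 (SD, n = 3 each). Rmrp was at 51370 ± 29590 TPM (SD, n = 3); the annotation holds a further gene ID of that name, so this is the ID with the higher mean. Of the mostly cytoplasmic non-coding RNAs, Rn7s1 and Rn7s2 had identical values of 10250 ± 4493 TPM (SD, n = 3), and these copies cannot be separated. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 were at 11.5 ± 7.88 and 5.52 ± 1.74 TPM (SD, n = 3 each). Vaultrc5 was listed at 0, 25.1 and 0 TPM in replicates 1, 2 and 3. Its value in replicate 2 came from 3 expected counts, at the floor for its length.

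Shares of TPM differed from shares of counts because TPM divides by length. snoRNA genes held 43.6 ± 5.59% of TPM and 0.416 ± 0.12% of counts, snRNA genes 13.9 ± 7.13% of TPM and protein-coding genes 22 ± 4.65% of TPM (SD, n = 3 each). Apart from Rmrp, the highest non-coding genes by TPM in the gene table were the snoRNA genes Gm22988, Gm26447, Snord22 and Snord15b. Gm22988 was at 126900, 69450 and 85240 TPM in replicates 1, 2 and 3. In the second quantification its mean was 12730 TPM, below Gm26917 at 36850, Rmrp at 23410 and Malat1 at 20250 TPM. An mRNA's TPM thus also moves with the share of small RNAs in its library. The median deviation of 10251 protein-coding genes from the mean of the libraries was 0.11, -0.36 and 0.26 (log2 TPM) in replicates 1, 2 and 3, and deviations of lists are therefore given relative to lists of genes of the same expression, which carry such shifts too. Values stated in TPM carry this shift; single genes are compared between libraries below after scaling to protein-coding TPM.

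**Figure D3:**
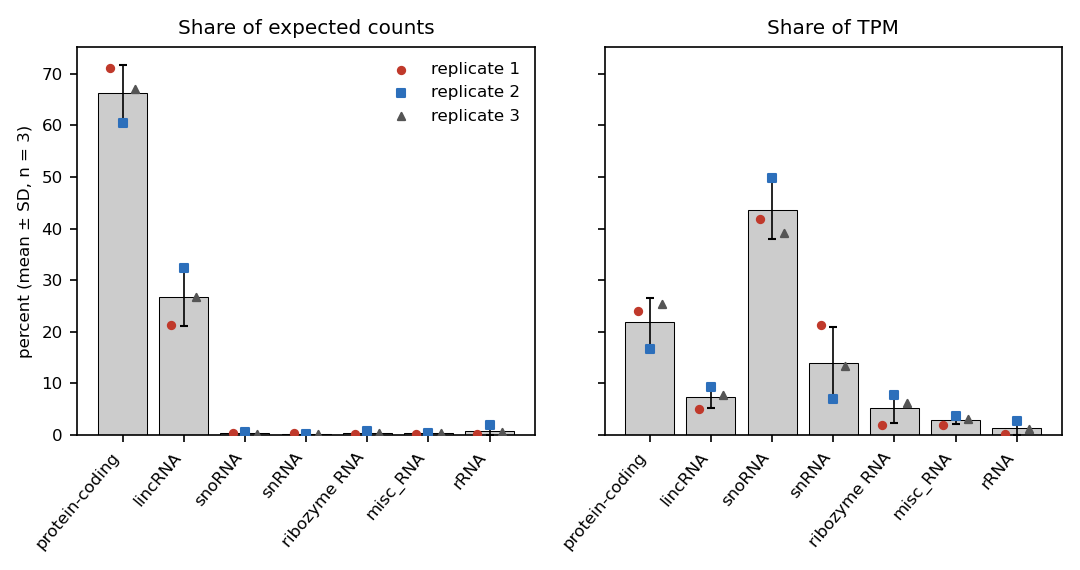
Shares of expected counts (left) and of TPM (right) by class of gene, in percent of annotated genes; bars are means, error bars SDs and points the 3 libraries. Protein-coding genes hold 66.3% of counts and 22% of TPM, and snoRNA genes 0.416% and 43.6%.

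Within protein-coding genes, isoforms annotated as retaining an intron held 39.3 ± 2.53% of TPM and protein-coding isoforms 47.7 ± 2.65% (SD, n = 3 each). These are estimates for spliced and unspliced models, not counts of introns. In expected counts the retained-intron share was 25.1 ± 3.71% (SD, n = 3), at 28.7%, 21.28% and 25.25% in replicates 1, 2 and 3. Among response genes with such an isoform, it held 97.7 ± 0.995% of the TPM of Dusp1, 79.5 ± 5.19% of that of Il1b, 78.8 ± 6.19% of that of Cxcl2 and 7.79 ± 2.41% of that of Nfkbia (SD, n = 3 each). The median share was 80.6 ± 3.93% for 5 early cytokine genes and 47.6 ± 3.2% for 6506 protein-coding genes (SD, n = 3 each). It was 69.2 ± 2.54% for 24 ribosomal protein genes (SD, n = 3), so a high share was not particular to the cytokines. The other deposited quantification gave 55.7 ± 6.33% for the early cytokine genes, 45.6 ± 1.66% for all, 50.7 ± 10.5% for Il1b and 39 ± 2.3% for Nfkbia (SD, n = 3 each). Isoform shares of genes and lists thus depend on the quantification.

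Levels were similar between libraries across genes. Pearson's r of log2(TPM + 1) across protein-coding genes, which are not independent replicates, was 0.9758 for replicates 1 and 2, 0.9885 for 1 and 3 and 0.9856 for 2 and 3. Spearman's rho was 0.9666, 0.9751 and 0.9741. The chi-square of the counts per degree of freedom was 83.1, 21.8 and 39.2 for the same pairs. Repeated sequencing of a library would give values near 1, so no libraries were counted as repeats of each other; the values do not measure how far biological replicates differ. The common biological coefficient of variation from edgeR was 0.2627 over 14205 genes.

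The inflammatory lists were highest in replicate 1. Relative to lists matched on expression, early cytokines deviated by 1.05 in replicate 1, -0.65 in replicate 2 and -0.32 in replicate 3 (log2, at percentiles 100.0, 0.0 and 0.0). Of the 13 members with a mean TPM of at least 1, 13 were highest in replicate 1 after scaling to protein-coding TPM, against 35.2% of all 10251 such protein-coding genes. On that scale the highest library exceeded the lowest by 33.7-fold for Tnfsf9, 7.07-fold for Cxcl1, 6.1-fold for Il1b, 6.06-fold for Ptgs2 and 4.82-fold for Tnf. NF-kB genes deviated by 0.65, -0.42 and -0.27, with 18 of 22 members highest in replicate 1, among them Nfkbiz (7.91-fold) and Socs3 (9.8-fold). Rapid early genes deviated by 0.33, -0.09 and -0.22, with 21 of 29 highest in replicate 1. Replicate 2 lay between the others in this list, at 0.09 without replicate 1, called high, and at -0.25 without replicate 3, called low. With GC content and length matched it was at -0.26, called low. Scaled to a sum of 1000000 over protein-coding genes, Egr1 was at 463, 246 and 99.7, whereas Fos was at 1056, 1874 and 1172. Interferon response genes deviated by 0.27, -0.37 and 0.02, with Gbp5 at 269, 16.6 and 57.3 on that scale, and secondary response genes by 0.23, -0.16 and -0.03. Without replicate 1, replicates 2 and 3 differed from their mean by -0.09 and 0.09 for early cytokines, at percentiles 7.1 and 92.9, which is not called. NF-kB genes were at -0.09 and 0.09 without replicate 1, not called either. Interferon response genes in replicate 3 were at 0.18 without replicate 1 and at -0.1 without replicate 2, called on opposite sides.

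The macrophage list deviated by -0.02, 0.08 and -0.04 and the TLR4 list by 0.02, -0.01 and 0.0 in replicates 1, 2 and 3, and neither was called in any library. With TMM scaling, DESeq2 size factors or the other quantification, the macrophage list was called low in replicate 3, at -0.07 in each. Ribosomal protein genes went the other way from the cytokines, at -0.34, 0.33 and 0.06, with 28 of 31 members lowest in replicate 1; the value of replicate 3 was -0.04 with TMM scaling and -0.05 with DESeq2 size factors. Histone genes were at -0.57, 0.55 and -0.01, with 10 of 10 members of mean TPM of at least 1 lowest in replicate 1. Without replicate 1, the histone list in replicate 3 was at -0.31, and without replicate 2 at 0.29. Housekeeping genes deviated by -0.1, 0.24 and -0.14, and by -0.05 in replicate 3 without replicate 2, not called. RNA processing genes deviated by 0.13, -0.11 and 0.05, and in replicate 1 by 0.04 without replicate 2 and 0.03 with GC content and length matched, neither called. Mitochondrial mRNAs were at 0.28, 0.39 and -0.54. In replicate 3, mt-Nd4l and mt-Atp6 were listed at 0 TPM, although the other quantification gave them 21.1 and 27.4 TPM in that library. Without replicate 3 the mitochondrial list was at 0.01 and -0.01, not called, and with GC content and length matched its value in replicate 1 was 0.1, not called. The other cell type, proliferation and stress lists deviated by at most 0.18 in size, the value of T and NK cell markers in replicate 3, called high. Erythroid and stromal markers were called low in replicate 1 and high in replicate 2. Small deviations of low genes can hide larger differences, since log2(TPM + 1) understates them. The stromal marker Col1a2 had 0, 75 and 18 expected counts in replicates 1, 2 and 3, whereas Kdr had 240, 213 and 238. Neutrophil, proliferation and stress genes were called low in replicate 3. B cell, dendritic cell and mast cell markers were not called in any library. In all, 32 of 63 pairs of list and library were called, against 3.15 for random lists. The deviations of a list are taken from the mean of the same libraries, so a high library lowers the others. These pairs are therefore not separate results. Starting RNA differed between the replicates and cannot be separated from the library.

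**Figure D4:**
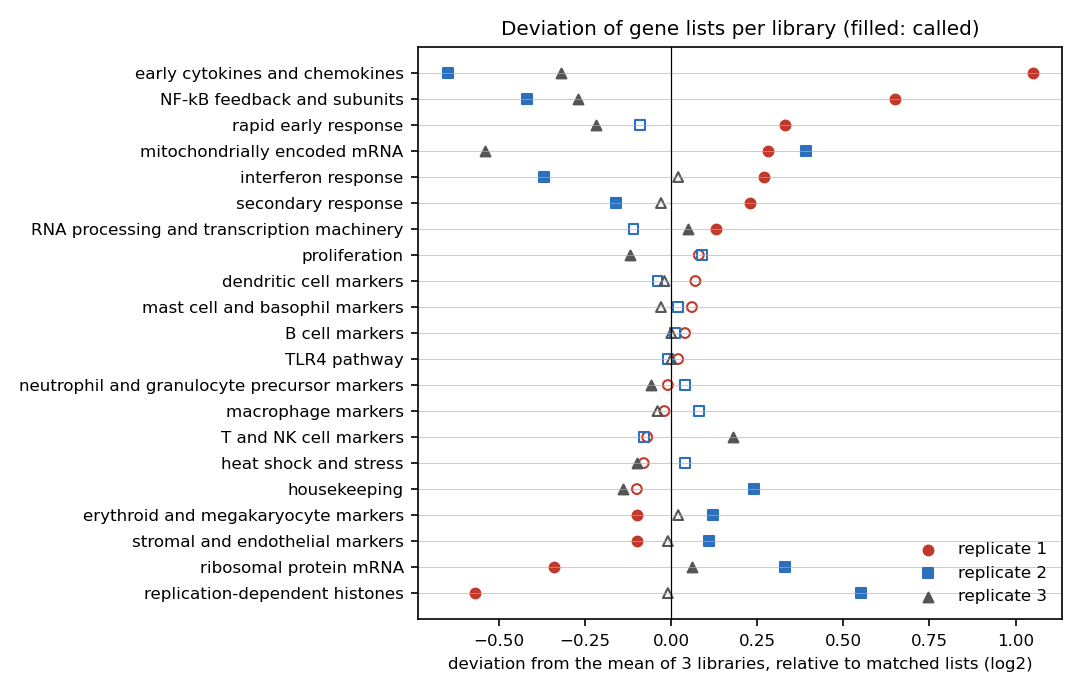
Deviation of each list's genes from the mean of the 3 libraries, relative to expression-matched lists (log2); each point is 1 library, filled where the value lies in the lowest or highest 2.5% of matched lists. Early cytokines stand at 1.05 in replicate 1, and histone and ribosomal protein genes at -0.57 and -0.34.

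The other deposited quantification gave more similar gene levels than isoform levels, though single genes such as Lgals3 differed widely. Across 22028 protein-coding genes, Pearson's r between the quantifications was 0.938, 0.945 and 0.935 in replicates 1, 2 and 3. Across 141767 transcripts it was 0.746, 0.748 and 0.736. Fos was at 546 ± 31.9 TPM, Nfkbia at 411 ± 256 TPM, Il1b at 212 ± 246 TPM and Tnf at 112 ± 104 TPM in it, and Il6 was at 0.426 ± 0.482 TPM (SD, n = 3 each). It gave the Y-linked genes Uty 8.24 ± 3.49 TPM, Kdm5d 5.38 ± 2.6 TPM and Ddx3y 1.51 ± 0.628 TPM (SD, n = 3 each), whereas the gene table gave Uty and Ddx3y 0.00333 ± 0.00577 TPM each and Kdm5d 0 TPM.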

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

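The data outside the annotated genes held counts above the floor of 3, and no control library could set a background for them. The phiX genome, a sequencing control, took 1.83% of the expected counts in replicate 1 (Wilson 95% interval 1.82 to 1.84%), 0.366% in replicate 2 (0.363 to 0.368%) and 0.476% in replicate 3 (0.472 to 0.48%). Features with numeric IDs, which were not matched to the annotation, held 46, 31 and 27 expected counts in replicates 1, 2 and 3. With 3 libraries in the group, single libraries were not tested as outliers.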

How the results depend on the processing

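Protein-coding scaling, matching on GC content and length, and leaving replicates out of the deviations were chosen after the data were seen. Rapid early minus secondary response stayed between 3.66 and 5.99 and ribosomal protein minus RNA processing between -4.61 and -2.74 in all 9 alternatives each, every one called. Of 195 alternatives for list levels, 189 kept the call. Of 544 for list deviations, 474 kept it, 30 lost it, 26 gained it and 14 changed direction. The count of 32 called deviations ranged from 26 to 33, the lowest among 42 pairs tested on genes with a mean TPM of at least 1.

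With lists and background limited to genes with a mean TPM of at least 0.1, the secondary response list (17 of 20 members left) stood at percentile 0.16, the neutrophil list (7 of 16) at 0.05 and the stromal list (10 of 16) at 0.0, all called low. The B cell, mast cell and Y-linked lists gave no value there, with fewer than 5 members left. The B cell list was called low in the second quantification (0.79). On TMM-scaled counts per 1000000, which do not divide by length, mitochondrial mRNAs lost the high call (95.52) and early cytokines minus interferon response reached -1.66. When leaving out a replicate, early cytokine level percentiles ran from 97.3 without replicate 1 to 99.98 without replicate 2, the latter called high. The percentile was 96.61 on TMM-scaled counts and 89.23 with genes limited to a mean TPM of at least 0.1 (16 of 19 members left), neither called.

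For deviations, rapid early genes in replicate 2 became called among genes with a mean TPM of at least 1 (-0.17) and with GC content and length matched (-0.26). Ribosomal protein genes in replicate 3 gave -0.04 with TMM, -0.05 with DESeq2 size factors, 0.03 in the second quantification, and 0.05 with a pseudocount of 0.1, protein-coding scaling, or GC content and length matched; the cause was not tested. Leaving out a replicate leaves 2 libraries whose deviations mirror each other. The ranges were then -0.25 to 0.09 for rapid early genes in replicate 2, -0.51 to -0.09 and -0.45 to 0.09 for NF-kB genes in replicates 2 and 3, and -0.86 to -0.09 and -0.64 to 0.09 for early cytokines in replicates 2 and 3. Since both libraries cannot be low then, this does not test whether the low values rest on the library left out. In replicate 3 the ranges were -0.1 to 0.18 for interferon response, -0.13 to 0.17 for ribosomal protein, -0.31 to 0.29 for histone, -0.09 to 0.13 for erythroid, -0.05 to 0.11 for stromal, -0.08 to 0.02 for stress and -0.04 to 0.08 for RNA processing genes. They were -0.01 to 0.37 for mitochondrial mRNAs in replicate 2 and -0.04 to 0.07 for neutrophil markers in replicate 1.

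At a TPM of at least 5, 5664 protein-coding genes were detected in all libraries. The lowest Pearson r was 0.9341 among genes with a mean TPM of at least 1, and 0.9758 to 0.9885 when leaving out a replicate. In expected counts and in the second quantification, retained-intron isoforms held 25.1% and 34.2%, snoRNA genes 0.416% and 9.56%, and protein-coding genes 66.3% and 37.4%. The coefficient of variation was 0.196 to 0.336 when leaving out a replicate. Depth limits the genes near 3 counts, such as Ifnb1, for which no difference between libraries was detectable.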

Other observations

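The neutrophil, snoRNA and ribosomal RNA tests were chosen after the values were seen; the GC content and mature RNA tests were written after the pattern was seen but before their own results. Scaled to a sum of 1000000 over protein-coding genes, Egr1 was at 463, 246 and 99.7, Egr2 at 166, 47.8 and 20.0 and Egr3 at 42.8, 26.3 and 8.61 in replicates 1, 2 and 3, each lowest in replicate 3. Of 29 rapid early genes, 12 were lowest in replicate 3 and 11 in replicate 2. Of 13 early cytokine genes, 10 were lowest in replicate 2 and 3 in replicate 3, among the latter Ccl4 at 268, 158 and 142. Fos, at 1056, 1874 and 1172, and Fosb, at 187, 342 and 202, were lowest in replicate 1. Clec4e, a receptor gene, was at 236, 25.5 and 74.4 and Arl5c at 264.5, 39.8 and 86.9; both are among the 10 genes with the largest SD. These genes were set side by side after their values were seen, and their order was not tested.

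The early cytokine list was higher in replicate 1, by 1.05 relative to matched lists (log2), and by 0.64 without replicate 2 and 0.86 without replicate 3. GC content or length bias across coarse bins is argued against as the whole cause. Lists matched on 3 bins of GC content, 3 of length and 10 of expression left 0.95, at percentile 100.0. Bias within these bins was not covered. More mature RNA in some libraries could lower nascent transcripts and raise ribosomal protein and histone mRNAs. It was tested by matching genes on their replicate 2 to replicate 3 difference, taken as that axis. For early cytokines in replicate 1, 0.98 remained, at percentile 100.0. Other lists in replicate 1 moved both ways. Ribosomal protein genes went from -0.34 to -0.2 and interferon response genes from 0.27 to 0.11, still called high. Mitochondrial mRNAs went from 0.28 to 0.6. The test cannot decide, since the axis leaves out replicate 1, where the pattern lies. Retained-intron isoforms held 28.7%, 21.28% and 25.25% of counts in replicates 1, 2 and 3, the same order of libraries as for early cytokines. A difference in mature RNA between the libraries therefore stays open. Neutrophils, a source of Il1b and Cxcl2, are argued against: 16 neutrophil markers together made up 1.07% of the gain of Il1b in replicate 1 in the gene table and 2.48% in the second quantification. S100a8 and S100a9 had 0 TPM there in the gene table, and 0.416 and 0 TPM in the second quantification. Also open are the amount of starting RNA, the handling of each fractionation and a stronger or more advanced response of that culture, which the design does not separate; with 1 group, no biological explanation was tested.

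The large snoRNA share of TPM may come from the very small effective lengths of short RNAs in the deposited tables. Recomputing TPM from the expected counts with full lengths gave snoRNA genes 6.89 ± 1.82% (SD, n = 3), against 43.6 ± 5.59% as deposited. The second quantification gave 9.56 ± 2.3% (SD, n = 3). An earlier test on effective lengths was set aside, since 1466 to 1477 of 1507 snoRNA genes met its condition and it could not have come out otherwise. For the same reason the recomputed share was bound to fall. It gives the size of the effect of length and is no test of the explanation. No biological explanation was tested.

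Gm26917 and Gm42418 took 4.4 and 5.11 times as large a share of counts in replicate 2 as in replicate 1, whereas Malat1, Neat1, Xist and Kcnq1ot1 took 0.737, 0.533, 0.755 and 0.701 times. A candidate explanation is ribosomal RNA left after depletion. The annotated rRNA gene CT010467.1, on chromosome 17 from 39846353 to 39848827 on the minus strand, put the libraries in the same order, at 0.138%, 1.89% and 0.545% of counts in replicates 1, 2 and 3. It shares 0 bases on its own strand with either gene: Gm26917 ends just before it at 39846341, and Gm42418, from 39846958 to 39848788, lies opposite to it on the plus strand. The absence of overlap on the same strand had been set to count against the explanation and the order of libraries went with it. The use of strand in counting is not given in the sources used here, so ribosomal RNA left over cannot be told apart from a difference in these transcripts. No biological explanation was tested.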
